A study of Caenorhabditis elegans with 2 samples.

How the data were processed

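Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole late embryos of transgenic Caenorhabditis elegans, per the labels. The worms expressed UNC-42 with a GFP-FLAG tag at its C terminus, per the labels as well. The labels' description names an antibody against GFP for the recovery of chromatin, while their antibody entry names unc-42, and the description is followed here. UNC-42 is a homeodomain transcription factor known for its role in the identity of sensory, inter- and motor neurons. There were 2 biological replicates of 1 group, collected 3 hours after synchronisation by egg bleaching. Each replicate was labelled as a separate biological sample. There was no second condition, so no comparison between conditions was made.

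The deposited data were lists of peaks in narrowPeak format, on the ce10 and the ce11 genome builds. Per the deposited text files that accompany the lists, each build had a list for each replicate, a list for the pooled replicates and a set that passed the optimal threshold of the irreproducible discovery rate (IDR). IDR judges how well the ranks of peaks repeat between replicates. The replicate and pooled lists were relaxed lists made as input for IDR, so they hold background regions as well as peaks, per the deposited text files. The same text files name 1 control file per build behind the replicate lists and the pooled list. The control was not analysed here. The aligner, the peak caller and their versions are not given in the sources used here. All 8 lists had the checksum that the text files give for them.

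The deposited signal value of each peak is the score the authors' peak caller gave it, on a scale of its own in each list, and it was used here to rank peaks within a list. The deposited −log10 q value of each peak reached a ceiling that 76.9% of the optimal ce11 peaks shared, so it was not used for ranking. Peak positions were taken from the deposited summit offset and are given 1-based. No read counts were used here, so the depth of each sample is unknown and no error per peak can be given. The intervals printed are 95% exact Clopper-Pearson intervals of shares of peaks or genes, and they treat these as independent, so they cover counting error only.

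Positions were compared with Ensembl release 115 annotation of WBcel235, which is the same assembly as ce11, and with the RefSeq sequence of that assembly. The annotation held 19973 protein-coding genes on the 6 nuclear chromosomes. The ce10 lists were used for counts and shares only, and no coordinates were converted. Annotation classes were assigned in the order 5' UTR, coding exon, 3' UTR, intron, gene of another biotype, intergenic.

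Replicates were compared over the 4780 highest-signal peaks of each replicate list, the number of optimal peaks, with summits within 100 bp counted as shared. Chance overlap, the share of summits near gene starts and the share in each annotation class were each set against 1000 circular shifts of the summits along their chromosomes. The smallest two-sided p these shifts can give is 0.002. Chromosome shares were set against the share of protein-coding gene starts with an exact binomial test. A gene was counted as having a peak when its 5' end was the nearest to an optimal summit and within 2000 bp of it. The share of genes with a peak in each of 20 gene lists was compared by permutation with 10000 random gene lists matched on the decile of upstream intergenic length, two-sided, and the smallest p that this test can give is 0.0002. The lists were glutamate receptors, neurotransmitter synthesis and transport, acetylcholine receptors, FMRFamide-like peptides, neuropeptide-like proteins, homeobox factors, immunoglobulin and other adhesion proteins, axon guidance, innexins, pan-neuronal and synaptic vesicle genes, ciliary genes, body wall muscle, intestine, hypodermis and cuticle, pharynx, germline, ribosomal proteins, chemoreceptors, nuclear hormone receptors and histones. Of their members, 9 genes stood in more than 1 list, and 2 symbols were not found in the annotation.

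Sites for 13 sequence motifs were searched on both strands in a window reaching 100 bp to each side of each summit and in windows of the same width centred 1000 bp to the left and right. Centre and flank were compared peak by peak with the exact McNemar test, and the larger p of the left and right comparisons was kept. Trends with rank used a permutation test with 100000 resamples, and shares of peak groups used Fisher's exact test, two-sided. P-values were adjusted by the Benjamini-Hochberg method within each family of tests, with a threshold of 0.05. With peaks or genes as the units, these p-values describe these 2 samples.

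The genes named are the nearest gene of each of the 10 highest-signal optimal peaks, up to 3 genes with a peak and the highest signal in each list, and unc-42, unc-119, glr-1, nmr-1, unc-17, cho-1, eat-4 and rig-3, with values given first for lists past the test. This rule, the gene lists, the motifs and the main tests were fixed before the data were examined. Alternatives were other distances and overlaps, a stricter peak set, either replicate alone, other ways to assign genes, unmatched tests, other windows and flanks, and dinucleotide shuffles (100 per peak window). Merged intervals, transcript 5' ends, a background without 2 large gene families and peaks without GA repeats were added after seeing the data. So was the comparison of the pan-neuronal list with the ribosomal list.

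On simulated data, 20 of 20 gene lists of 40 genes whose members were given a peak with a chance of 50% passed the list test among 19973 genes, and 0 of 200 random lists did. Members were drawn at random and kept the peaks they already had. Smaller shares and lists of neighbouring genes were not simulated. For the replicate overlap, 59.7% of 4780 summits were kept in a simulated second list and 59.8% were recovered. For the motif test, 39 of 4780 windows at random positions had a site, with an exact p = 1. Sites planted in 1.76% of these windows, on top of the natural ones, raised the count to 124 (exact McNemar p = 3.98e-10). A smaller excess was not simulated. The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.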

Results

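GFP ChIP-seq signal of tagged UNC-42 was mapped as peaks in whole late embryos of transgenic C. elegans, in 2 biological replicates of 1 group. No sample without the tag or with another tagged protein was analysed, so the peaks are not shown to be specific to UNC-42. The replicate 1 list held 22676 regions and the replicate 2 list 20932 on ce11 (WBcel235), and the pooled list held 23778. The set that passed the optimal IDR threshold held 4780 peaks with a median width of 456 bp. Read depth is unknown, so the number of regions in a list is not a measure of how well a replicate was sequenced.

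The first question was how well both replicates placed the same sites. The strongest sites were shared. The peak upstream of zoo-1, which encodes a junction protein of the zonula occludens family, ranked 2 in replicate 1 and 1 in replicate 2, and the peak at C37A2.8 ranked 1 and 2. Of the 4780 highest-signal summits of replicate 1, 3657 lay within 100 bp of one of the 4780 highest of replicate 2, which is 76.5% (95% interval 75.3 to 77.7%). Circular shifts gave 0.996% on average and at most 1.46% (permutation p = 0.002, the smallest that 1000 shifts can give). The shifts stand for random positions only. Both lists were made with the same control file, and how much agreement a shared control or background regions common to both samples would bring was not tested. Across the 4596 optimal peaks found in both replicate lists, log2 signal correlated with Spearman's rho = 0.787 and Pearson's r = 0.822, a relation across peaks, which are not independent replicates. By signal, the optimal set was the first 4780 entries of the pooled list, and the entries outside it began at rank 4781. Its peaks were thus selected on the pooled signal of both replicates, and the 4596 also on their presence in both lists. The correlation depends on that selection and is not an independent measure of agreement. Of the 4780 optimal peaks, 83 (1.74%) lay in the top 4780 of neither replicate.

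**Figure D1:**
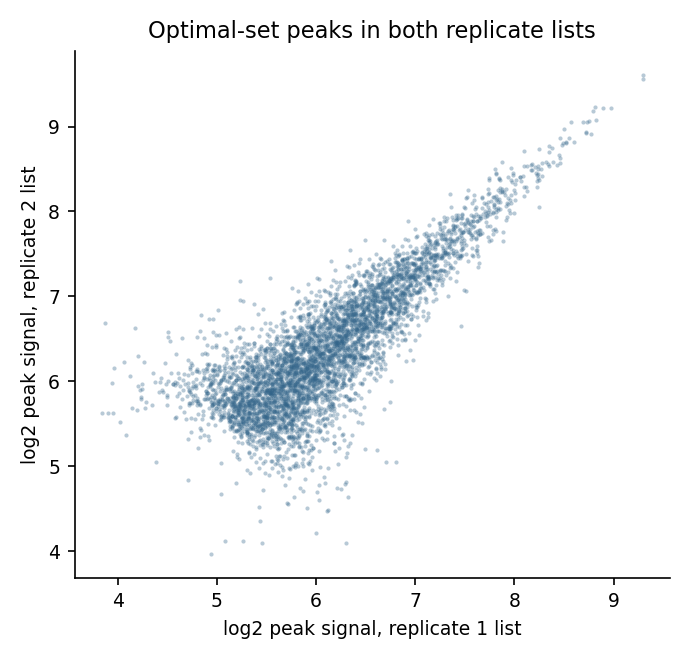
Each point is 1 of the 4596 optimal peaks found in both replicate lists, with log2 signal in the replicate 1 list on the x axis and in the replicate 2 list on the y axis, each on its own list's scale. The points rise together, with Spearman's rho = 0.787.

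The next comparison asked where in the genome the peaks lay. Intergenic sequence held 2821 of the 4780 summits, and introns held 1348. Intergenic summits made up 59.0% against 33.2% after circular shifts, 5' UTRs 3.24% against 1.78%, and genes of biotypes other than protein-coding 6.38% against 3.8%. Coding exons were depleted, with 1.74% of summits against 24.1%. Introns (28.2% against 33.7%) and 3' UTRs (1.42% against 3.37%) lay below the shifted shares as well. Each of these 6 shares differed from its shifted share with an adjusted p of 0.002 by permutation. Within 1000 bp of a protein-coding 5' end lay 2104 summits, 44% (95% interval 42.6 to 45.4%), against 34% after shifts (permutation p = 0.002).

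Peaks were spread unevenly over the chromosomes. Chromosome X carried 1048 peaks, 21.9% of the total, where its share of protein-coding gene starts was 13.7% (ratio 1.60, adjusted p = 1.35e-53, exact binomial test). Chromosome V carried 678 peaks, 14.2% against 25% of gene starts (ratio 0.567, exact binomial adjusted p = 2.54e-74). Chromosomes I and III lay above their shares, with ratios of 1.25 (exact adjusted p = 1.31e-11) and 1.17 (adjusted p = 6.52e-06). Chromosomes II and IV lay below, with ratios of 0.883 (exact adjusted p = 0.000228) and 0.919 (adjusted p = 0.0132). At 4780 peaks each, the replicates had 22.3% and 22.3% of peaks on X and 14.3% and 14.1% on chromosome V. Against chromosome length in place of gene starts, the ratio of X fell to 1.24 and that of V rose to 0.680. The ratios of I, III and IV were then 1.20, 1.13 and 0.866, and that of chromosome II was 1.00 (exact binomial adjusted p = 0.984). The size of the excess on X and of the deficit on V thus depended on the baseline.

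The highest-signal peaks stood near genes of varied function. The strongest had a pooled signal of 1404 and its summit on chromosome I at 14528804, in intergenic sequence 725 bp upstream of zoo-1 (14529529 to 14546870). The second, with a signal of 1377, lay 57 bp upstream of C37A2.8 (I, 6798227 to 6799608). The third, with a signal of 1094, lay 717 bp upstream of egg-5, an egg activation gene (I, 4168984 to 4171589), inside a gene of another biotype. The fourth lay in an intron of unc-75 (I, 11592246 to 11601712), an RNA-binding protein of the nervous system, 3035 bp inside the gene, with a signal of 1070. An intronic peak of lin-2 (X, 12399517 to 12414041), a scaffold protein, had a signal of 1004 and lay 6533 bp inside the gene. The peak ranked 6 was nearest to ncs-2 (I, 10033280 to 10034816), a neuronal calcium sensor gene, and lay in an intron of ercc-1, with a signal of 1022. The peak ranked 8 lay 94 bp upstream of sol-2 (I, 14721742 to 14725967), an auxiliary subunit of glutamate receptors, with a signal of 954. Its summit was in a coding exon, within the body of K05C4.10. The remaining peaks of the first 10 were nearest to F19C7.3 at 10936 bp, K12H4.5 at 507 bp and mrck-1 at 336 bp. The summit nearest to F19C7.3 was in an intron within F28E10.1, and that of mrck-1 inside a gene of another biotype. All of these peaks were in both replicate lists, at ranks between 1 and 13.

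Genes of the nervous system were then examined by the lists fixed in advance. Of the 19973 protein-coding genes, 2492 (12.5%) had a peak by the 2000 bp rule. The rule left 1900 of the 4780 summits (39.7%) without a gene. Within 2000 bp of a 5' end lay 60.3% of summits, little more than the 56.5% after circular shifts (ratio 1.07, permutation p = 0.002). Pan-neuronal and synaptic vesicle genes stood out, with a peak at 26 of 31 (83.9%, 95% interval 66.3 to 94.5%). Axon guidance genes had a peak at 18 of 39 (46.2%), glutamate receptors at 8 of 19 (42.1%), and immunoglobulin and other adhesion genes at 18 of 50 (36%). Outside the nervous system, ribosomal protein genes had a peak at 35 of 76 (46.1%). Against matched random lists, by permutation, these shares were 5.68 times the random share (adjusted p = 0.001), 2.94 times (adjusted p = 0.001), 3.25 times (adjusted p = 0.00971), 2.24 times (adjusted p = 0.004) and 3.57 times (adjusted p = 0.001), in the order given. The pan-neuronal and ribosomal shares were also compared with each other, after the results were seen and without matching on upstream length. The pan-neuronal share was above the ribosomal share (odds ratio 6.09, Fisher's exact p = 0.000456), but not detectably so when gene bodies with 2000 bp upstream were counted. That count gave 29 of 31 pan-neuronal and 62 of 76 ribosomal genes (81.6%, odds ratio 3.27, Fisher's exact p = 0.144). In the 2390 peaks with the highest signal, adhesion genes no longer passed (1.99 times, permutation adjusted p = 0.175).

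**Figure D2:**
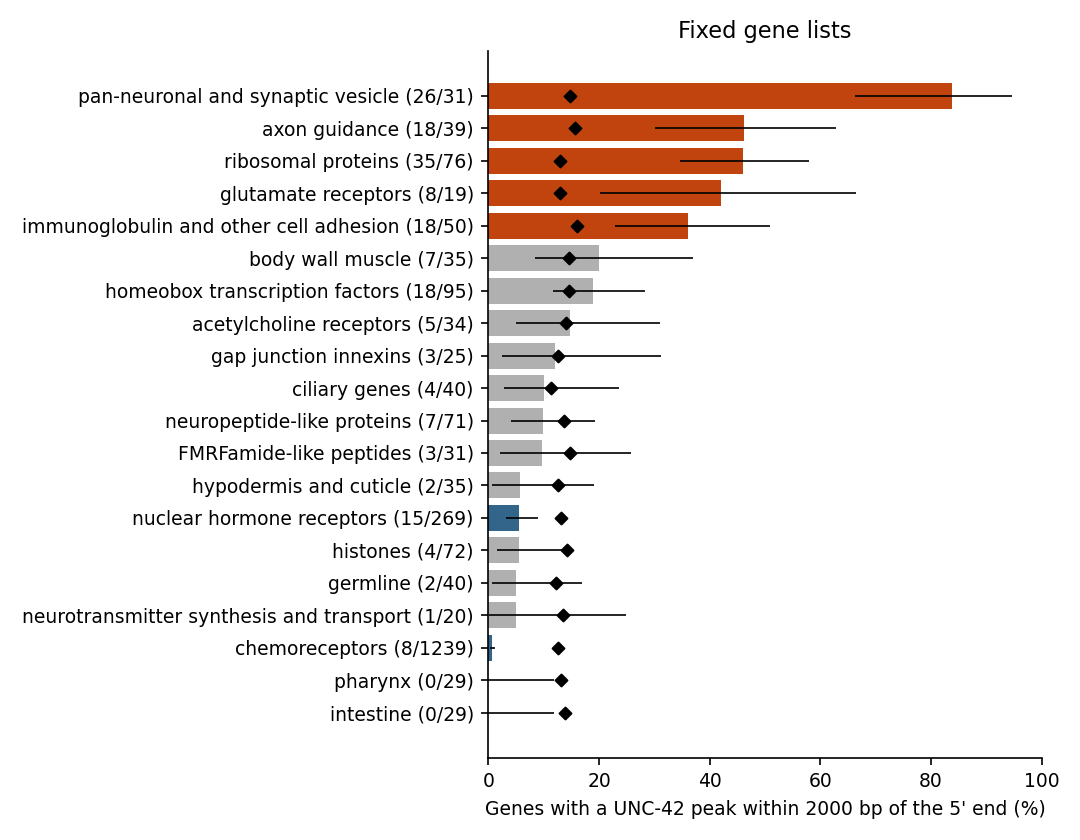
Bars show the percent of genes in each fixed list with an optimal peak within 2000 bp of the 5' end, with exact 95% intervals as lines and the mean of matched random lists as diamonds. Red bars lay above and blue bars below the random lists with an adjusted p under 0.05, from 83.9% of pan-neuronal genes to 0.646% of chemoreceptors, and grey bars did not pass.

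Among the pan-neuronal genes, egl-3, the proprotein convertase that cuts neuropeptide precursors (V, 10169177 to 10173753), had the highest signal, 417 at rank 194, with its summit 1214 bp upstream. The active zone gene unc-10 (X, 7272317 to 7280322) had a signal of 365, with its summit 1241 bp upstream, and the axonal kinesin gene unc-104 (II, 6994987 to 7010625) a signal of 289. These 3 summits were intergenic. The 5 members without a peak were cpx-1, ida-1, unc-119, snb-1 and ric-4, named here after their values were seen. Among axon guidance genes, eva-1, which encodes a SLT-1 co-receptor (I, 14829732 to 14834841), had 4 peaks, the strongest with a signal of 910 at rank 13 in an intron. The peak of lin-18, a Ryk receptor gene (X, 3958552 to 3961907), had a signal of 689 and lay 747 bp upstream. That of mab-20, a semaphorin gene (I, 1644588 to 1651457), had a signal of 470 and lay 47 bp upstream.

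Glutamate receptor genes with a peak included glr-1 (III, 8584163 to 8588642), an AMPA-type subunit of command interneurons. Its summit lay 319 bp upstream, inside a gene of another biotype, with a signal of 381 at rank 256. It ranked 254 in the replicate 1 list and 267 in the replicate 2 list. The intergenic peak of glr-5 (V, 8716495 to 8720516), a kainate-type subunit, lay 133 bp upstream with a signal of 315. The glutamate-gated chloride channel gene avr-14 (I, 5967247 to 5973326) had 3 peaks, the strongest in an intron with a signal of 397. Among adhesion genes, igcm-4 (X, 2039397 to 2046360) had an intronic peak with a signal of 397, cdh-9 (X, 16595231 to 16602245) an intronic one with a signal of 277, and rig-1 (X, 8660619 to 8671827) an intergenic one with a signal of 269. Of the ribosomal protein genes, rpl-12 (IV, 13239587 to 13240651), rpl-3 (III, 3867854 to 3869587) and rpl-35 (III, 7855134 to 7855646) had intergenic peaks with signals of 908, 838 and 630, which lay 63, 273 and 456 bp upstream.

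Chemoreceptor and nuclear hormone receptor genes had few peaks. The chemoreceptor list held 1239 genes, without the srbc and srlf classes. Of these 1239 genes 8 had a peak (0.646%), 0.0511 times the matched random share (permutation adjusted p = 0.001), with sri-5, sre-23 and str-56 the strongest at signals of 369, 319 and 266. Of 269 nuclear hormone receptor genes 15 had a peak (5.58%), 0.427 times the random share (permutation adjusted p = 0.0016), with nhr-48, nhr-3 and nhr-1 the strongest at signals of 210, 207 and 172.

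The other 13 lists did not pass the permutation test. Homeobox genes had a peak at 18 of 95 (permutation adjusted p = 0.456), with lim-4, ceh-58 and ceh-38 at signals of 319, 296 and 264. Body wall muscle genes had one at 7 of 35 (permutation adjusted p = 0.607), the strongest at act-4, tni-1 and unc-60. Acetylcholine receptors had one at 5 of 34 (permutation adjusted p = 1), innexins at 3 of 25 (adjusted p = 1) and ciliary genes at 4 of 40 (adjusted p = 1), the strongest of these at klp-11, daf-19 and dyf-6. Among the 5 acetylcholine receptor genes were gar-2, acr-12 and unc-63, and the 3 innexins were unc-9, inx-19 and unc-7. Neuropeptide-like protein genes had a peak at 7 of 71 (permutation adjusted p = 0.607), with nlp-14 at a signal of 490, nlp-76 at 230 and nlp-4 at 224, and FMRFamide-like peptide genes at 3 of 31 (adjusted p = 0.727), which were flp-22, flp-1 and flp-5. Neurotransmitter synthesis and transport genes had a peak at 1 of 20, unc-17 (permutation adjusted p = 0.607), at 0 of 20 without replicate 1, and at 5 of 20 with a limit of 5000 bp. Hypodermis and cuticle genes had one at 2 of 35 (permutation adjusted p = 0.502), the collagen gene sqt-1 with a signal of 421 at rank 184, and let-413. Germline genes had one at 2 of 40 (permutation adjusted p = 0.428), nos-3 and cgh-1, and histone genes at 4 of 72 (adjusted p = 0.0748), the strongest at his-37, his-68 and his-62. Intestine and pharynx genes had one at 0 of 29 each (upper 95% limit 11.9%), with permutation adjusted p-values of 0.069 and 0.0748. Without replicate 1 the pharynx count was 1 of 29 and without replicate 2 it was 2 of 29 (upper 95% limit 22.8%), and without replicate 2 the hypodermis and cuticle count was 5 of 35 and that of acetylcholine receptors 8 of 34, with no such list passing.

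Genes named in advance for their link to UNC-42 or to the strain differed in their peaks. The vesicular acetylcholine transporter gene unc-17 (IV, 3618259 to 3624699) had an intergenic peak 1979 bp upstream, close to the limit of 2000 bp, with a signal of 298 at rank 491. No optimal summit lay within 2000 bp of the 5' end of the choline transporter gene cho-1, the vesicular glutamate transporter gene eat-4 or the immunoglobulin gene rig-3. The nearest lay 3933 bp upstream of cho-1, 3179 bp upstream of eat-4 and 2917 bp upstream of rig-3. For unc-119, a neuronal gene, the nearest optimal summit lay 2630 bp inside the gene from its 5' end. The relaxed pooled list, which also holds background regions, had weaker entries nearer to the 5' ends, at 1304 bp for cho-1, 872 bp for eat-4, 247 bp for rig-3 and 301 bp for unc-119. The NMDA-type receptor gene nmr-1 (II, 5440238 to 5446606) had its nearest optimal summit 15660 bp upstream. The nearest summit to unc-42 itself (V, 9764534 to 9769391) lay 26808 bp upstream, and no entry of the relaxed pooled list lay between 9734153 and 9796199, a stretch of 62046 bp. The same stretch was empty over 61972 bp in the replicate 1 list and 60102 bp in the replicate 2 list.

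**Figure D3:**
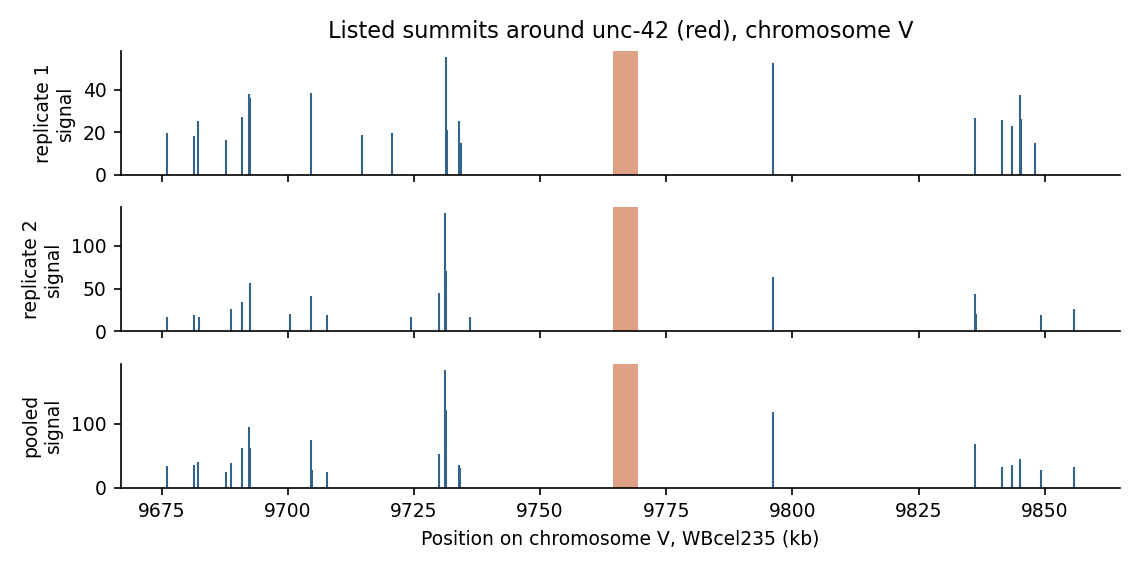
Vertical lines are listed summits on chromosome V in the replicate 1, replicate 2 and pooled lists, with their height the signal on each list's own scale, and the red band is unc-42. No summit lay within the 62046 bp around the gene in the pooled list.

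The number of genes with a peak depended on how peaks were assigned. Counting every gene with a 5' end within 2000 bp gave 3744 genes, counting gene bodies with 2000 bp upstream gave 3917, and the 2390 strongest peaks gave 1347. Replicate 2 alone gave 2467 genes, 2272 of them among the 2492, and replicate 1 alone gave 2484, with 2226 shared. The 7 lists that passed did so with each replicate alone.

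The last comparison asked which sequences lay under the summits. A palindrome of 2 homeodomain sites (TAAT) 3 bases apart, TAATNNNATTA, lay at 90 of 4780 summits (1.88%, 95% interval 1.52 to 2.31%), against 1.14% of flanking windows (ratio 1.65, adjusted p = 0.014, exact McNemar test). The scrambled control ATTANNNTAAT holds the same 2 sites 3 bases apart, facing the other way, so it controls for their orientation and not for their presence. It lay at 1.17% of summits and 1.15% of flanks (exact adjusted p = 1). Palindromes with 2, 4 or 5 bases between the sites had ratios of 0.844 (exact adjusted p = 0.737), 0.586 (adjusted p = 0.0744) and 0.871 (adjusted p = 1). The palindrome's call ended in the 2390 strongest peaks (ratio 1.42, exact adjusted p = 0.551) and in windows reaching 200 bp to each side of the summit (ratio 1.30, adjusted p = 0.319).

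The commonest difference was a GA repeat, GAGAGAGA, at 558 summits, 11.7% (95% interval 10.8 to 12.6%) against 2.19% of flanks (ratio 5.34, exact McNemar adjusted p = 5.24e-72). GATA sites were less frequent at summits, at 27.6% against 35.0% (exact adjusted p = 1.43e-11), and so was TATAAA, at 12.5% against 20.3% (adjusted p = 1.01e-22). GC content was 42% at summits and 36% in the left flanks, and against dinucleotide shuffles of the summit windows TATAAA was more frequent (ratio 1.18, permutation adjusted p = 0.0286). The core TAATTA (10.9% against 9.98%, exact adjusted p = 0.435), the E-box (55.4% against 53.4%, adjusted p = 0.248), the POU octamer (2.28% against 1.65%, adjusted p = 0.274), the COE site (0.209% against 0.146%, adjusted p = 1) and the X-box motif (0.0837% against 0.0732%, adjusted p = 1) did not pass.

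**Figure D4:**
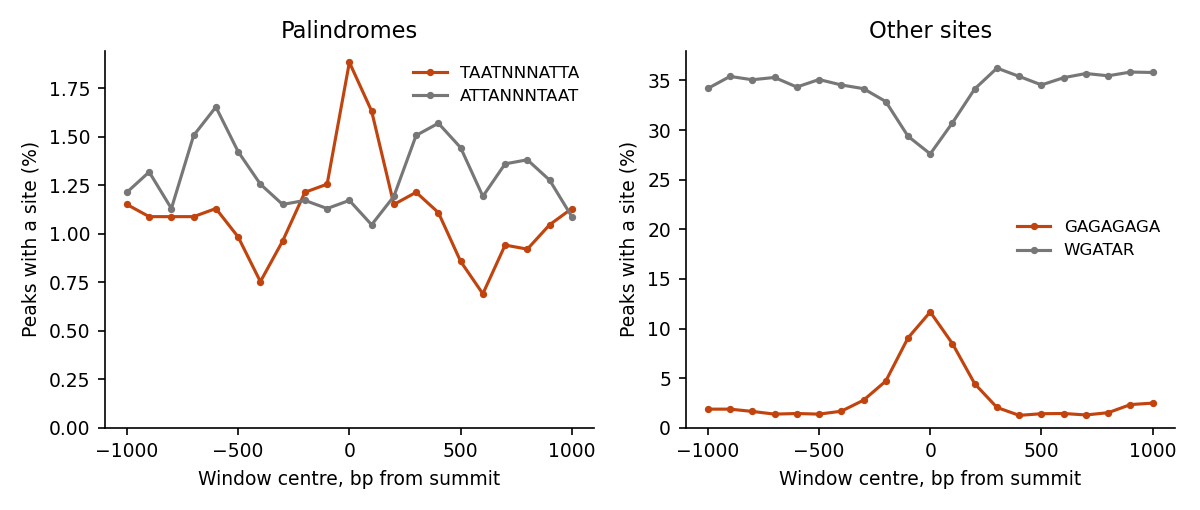
Percent of the 4780 optimal peaks with a site in windows reaching 100 bp to each side of their centre, by the distance of the window from the summit in bp, for the palindrome and its scrambled control in the left panel and for the GA repeat and GATA sites in the right panel. The palindrome reaches 1.88% and the GA repeat 11.7% at the summit, where GATA sites fall to 27.6%.

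No trend of the palindrome with peak strength was detectable. It lay at 21 of the 956 strongest peaks (2.20%) and at 20 of the 956 weakest (2.09%), and its presence did not vary detectably with signal (rho = -0.00073, permutation p = 0.96). Among summits in the top 4780 of both replicates 1.75% had it, against 2.09% of those in one alone (odds ratio 0.833, Fisher's exact p = 0.375). Neither comparison showed a detectable difference with this number of sites.

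Both genome builds gave lists of similar size. The optimal set held 4780 peaks on ce11 and 4741 on ce10, which is 99.2%. Replicate 1 had 22676 and 22372 regions, replicate 2 had 20932 and 20938, and the pooled list 23778 and 23781. No chromosome's share of a whole list differed by more than 0.166 percentage points between builds, and the largest difference among the 4780 highest-signal regions was 0.188 points, in replicate 1.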

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

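The sequences under the entries of the relaxed pooled list outside the optimal set were used in no comparison above, and their sites were counted after the other results were seen. Ranked by signal and divided into 4 groups of nearly equal size, they carried TAATNNNATTA more often than their flanks, which is why they are given here. The shares were 2.27% against 1.18% (adjusted p = 0.00401), 2.34% against 1.11% (adjusted p = 3.32e-05), 1.94% against 1.05% (adjusted p = 0.00785) and 1.92% against 1.11% (adjusted p = 0.00466), from the strongest to the weakest group, by the exact McNemar test over 12 comparisons. The GA repeat was above its flanks in the first 3 groups, at 6.61% against 2.21% (exact adjusted p = 1.83e-23), 4.29% against 1.86% (adjusted p = 6.3e-07) and 2.78% against 1.71% (adjusted p = 0.00747). In the weakest group it lay at 2.32% against 1.59% (exact adjusted p = 0.073). The scrambled palindrome passed in none of the 4 groups (exact adjusted p between 0.112 and 0.757), but it lay at 1.35% against 0.905% of flanks (ratio 1.49) in the second group and at 1.79% against 1.17% (ratio 1.53) in the third, where the palindrome's ratio was 1.84. The palindrome and its control were not tested against each other. In the optimal set the palindrome lay at 1.88% of summits against 1.14% of flanks (ratio 1.65), while the ratios of the groups outside it ran from 1.73 to 2.11. The palindrome was thus no more frequent in the optimal set than in the other listed entries, which include background regions. It does not mark the optimal peaks, and the difference between the sets was not tested.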

How the results depend on the processing

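The alternatives with merged intervals, transcript 5' ends, a background without chemoreceptors and nuclear hormone receptors, and peaks without GA repeats were chosen after seeing the data. The replicate overlap, promoter share and annotation shares kept their direction and their side of the threshold under every alternative run for them, and so did the chromosome shares other than that of II. The palindrome comparisons by rank and by replicate support stayed short of the threshold, with odds ratios by support from 0.707 to 1.58. The stricter set holds 2390 peaks by construction, gave 1347 genes with a peak, and lowered the palindrome's ratio to 1.42, where it no longer passed (exact adjusted p = 0.551). With windows reaching 200 bp to each side the ratio was 1.30 and did not pass, and the cause was not tested. Counting every gene within 2000 bp gave 3744 genes, since a peak can then count for several genes, and counting gene bodies gave 3917, which also takes in summits deeper in genes. The nearest gene within 5000 bp gave 3117. With summits matched within 200 bp, rho between replicates was 0.762. Against chromosome length, the ratio of chromosome II turned from below its share to 1.00. Against dinucleotide shuffles TATAAA turned from lower to higher, with a ratio of 1.18, and the cause was not tested. The scrambled palindrome also lay above shuffles (ratio 2.35), beside the palindrome's 3.73. The E-box passed with the narrower windows (ratio 1.09), with flanks 500 bp away (1.09) and against shuffles (1.08), and the core TAATTA (1.88), the POU octamer (1.61) and the 5-base palindrome (1.63) passed against shuffles. Among gene lists, the adhesion list no longer passed in the stricter set (1.99 times random). Histones passed against the background without those families (0.367 times) and without GA-repeat peaks (0.303 times), intestine genes passed at 0 times random with every gene within 2000 bp, with transcript 5' ends and without those families, and pharynx genes passed at 0 times with every gene within 2000 bp. No paired analysis was possible because there is a single group. Depth is unknown, and rare sites limit the palindrome comparisons.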

Other observations

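All tests in this part were chosen after the results were seen, except the counts of listed regions around unc-42 and unc-119. Among 91 gene classes defined by the letters of the gene symbol, with 20 or more members each, 11 had a peak more often than matched random lists and 20 less often. Many of these classes overlap the fixed lists and are not separate findings. The rpl and rps classes repeat the ribosomal list, while nhr, str and most of the sr classes below random repeat the receptor lists. Several unc genes with a peak stand in the pan-neuronal and axon guidance lists. The unc class, named for uncoordinated movement, had one at 45 of 94 genes (3.35 times the random share, permutation adjusted p = 0.00202). Large ribosomal subunit genes (rpl) had one at 23 of 45 (4.10 times, permutation adjusted p = 0.00202), and mitochondrial ribosomal mrps genes at 9 of 25 (3.41 times, adjusted p = 0.00569). The rab class of vesicle traffic GTPases had one at 8 of 20 (3.70 times, permutation adjusted p = 0.00637), vps genes of vacuolar sorting at 10 of 31 (3.10 times, adjusted p = 0.00607) and dnj chaperone genes at 12 of 29 (3.36 times, adjusted p = 0.00303). Among the classes below random were clec lectin genes at 8 of 240 (0.283 times, permutation adjusted p = 0.00202), fbxa F-box genes at 2 of 170 (0.0962 times, adjusted p = 0.00202) and ttr genes at 0 of 58 (adjusted p = 0.00693).

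Some long genes held many summits. Counting the gene body and 2000 bp upstream, kin-1, the catalytic subunit of protein kinase A, held 15 summits over 38.5 kb. The PDZ-domain gene mpz-1 held 12, and the cadherin gene hmr-1 held 10 over 58.9 kb. In a scan of 33 arrangements of 2 TAAT sites with 0 to 10 bases between them, the direct repeat TAATNTAAT lay at 3.68% of summits against 2.15% of flanks (ratio 1.71, exact adjusted p = 0.000835), and the palindrome with 3 bases passed in this family as well (exact adjusted p = 0.0355). The palindrome with 0 bases between its sites lay below its flanks (0.46% against 1.09%, exact adjusted p = 0.0101), and so did the direct repeat with 6 bases (1.13% against 2.17%, exact adjusted p = 0.0056).

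The region of unc-42 held no entry of the pooled, replicate or optimal lists on ce11. Before the data were examined, extra copies of a transgene that carries unc-42 were held to require more pooled entries in the surrounding 40 kb than the upper end of the central 95% of windows at other genes. There were 0 where that limit was 21 and the median 8, which argues against extra listed regions from such copies, while the 10 kb around unc-119 held 6, near its limit of 7 and above the median of 2 (96.1% of other genes had 6 or fewer), so extra copies of a marker at unc-119 stay open. A gap as long held 5.38% of other genes outside the chemoreceptor and nuclear hormone receptor families in the pooled list, 3.09% in the replicate 1 list and 4.73% in the replicate 2 list, so an ordinary long gap stays open. The midpoint of the pooled gap (V, 9765176) lay inside unc-42 itself. The gap held 3.06 gene starts per 10 kb, against 2.37 in the 56 other gaps as long and 1.99 over the genome. Of its 19 gene starts 0 belonged to those families, against 22.9% in the other gaps. These differences were not tested. Transgene copies that are present in the control as well may also hide peaks here, but the lists hold no read depth in the gap, and the 18 entries within 50 kb of its ends do not decide it.

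Peaks at pan-neuronal and at ribosomal protein genes may have technical or shared sources, and no biological explanation was tested against a second condition. Recovery of GA-repeat sequence whatever the tagged protein is argued against as the whole cause. Of the 34 pan-neuronal peaks 7 (20.6%) carried the repeat, which by itself argues against it as their whole cause. Counting peaks without a GA repeat left 23 pan-neuronal genes with a peak, 5.57 times the random lists (permutation adjusted p = 0.0008). With so few peaks to leave out, this ratio could not have fallen to 1, and it adds no separate test. Of the 37 ribosomal peaks 0 carried the repeat, which by itself argues against the repeat as their whole cause. Leaving out peaks with the repeat could therefore not lower the ribosomal count of 35, and the ratio of 3.77 (permutation adjusted p = 0.0008) adds no separate test. Neither list's share of peaks with the repeat stood apart from other peaks after adjustment (Fisher's exact adjusted p = 0.483 and 0.234). The 3-base palindrome lay within 100 bp of the summit at 0 of 71 peaks of these lists (upper 95% limit 5.06%), so direct binding at it was not their whole cause. Its share over all optimal peaks was only 1.88% and was known beforehand. The test could hardly have come out otherwise, and it does not set these peaks apart from the others. Binding at other sequences was not tested. Recovery of promoters active in most cells whatever the tagged protein stays open. By gene bodies with 2000 bp upstream, pan-neuronal genes exceeded ribosomal ones with an odds ratio of 3.27 and Fisher's exact p = 0.144, where the nearest-gene rule gave 6.09 and p = 0.000456.

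The low share of chromosome V and the high share of X were each set against 1 property of their genes. Chemoreceptor and nuclear hormone receptor families, as listed, are argued against as the whole cause on V, since outside them 8.46% of V genes had a peak against 14.7% of the other chromosomes' genes (odds ratio 0.535, Fisher's exact p = 4.44e-27). The chemoreceptor list holds no srbc or srlf genes, which had a peak at 0 of 71 and 1 of 36. These stayed among the genes outside the families, and the comparison was not repeated without them. Upstream regions on X were longer, with a median of 2112 bp against 825 bp, and 16.7% of X genes had a peak against 11.8% of other genes, though chromosomes I (16.6%) and III (16.3%) had nearly the same share as X. Matched on the decile of upstream length, X genes had a peak 1.23 times as often as random lists (permutation p = 0.0002, the smallest 10000 lists can give). Lengths can still differ within a decile, and genes with a peak were counted in place of peaks. Longer upstream regions may thus account for part, and this test cannot exclude them as the whole cause. Other gene families and regional differences in chromatin were not tested.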
